A study of Homo sapiens with 16 samples.

How the data were processed

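RNA was measured on Affymetrix whole-genome arrays in 4 AML cell lines, each treated with vehicle or with 0.5 µM AZA on 3 days followed by 4 days without drug, with 2 arrays per group and 16 arrays in all. Per the labels' protocols, cells grew in a light-labelled medium for mass spectrometry and RNA came from frozen cell pellets. The deposited values are log2 signals per probe set, made with affy and RMA per the submitters' processing notes, which give no versions, log base or order of steps. Every array shared the same quantiles to within 0.00404, with a median of 6.73 and values from 3.26 to 15.3, and the values were not centred per gene. They were used as deposited. The arrays carry no detection calls here, so changes of genes near the background are compressed. Having 2 arrays per group limits the precision, and the numbers of the replicates pair no arrays.

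The table held 54675 probe sets, of which 62 were array controls. With the gene annotation supplied for the arrays, 41097 probe sets had 1 gene symbol, 1801 several and 11777 none; 41043 were matched by gene identifier to a gene table of assembly GRCh38.p14, which changed 0 symbols. Probe sets with exactly 1 symbol were kept, and the probe set with the highest mean over the 16 arrays stood for each of 19775 genes. Genes were tested if their signal reached the array median on at least 2 of 16 arrays, which left 14049 genes, 8817 of them with more than 1 probe set. Probe sets of 1 gene can measure different transcripts, and for a number of named genes they differ. The lowest and highest values among probe sets, at least 2 of them bright, were 0.15 and 3.88 for HGD, -2.43 and 0.00 for CLEC7A, and -1.96 and 0.01 for NCAM1 in HNT-34. In KG1a they were 0.84 and 6.77 for COL14A1, -1.40 and 0.20 for SHANK2, and -0.12 and 2.01 for ITGA2B. In HL60 they were 0.89 and 3.84 for CD93, -3.61 and -1.04 for PSAT1, -2.43 and -0.11 for AJUBA, -0.20 and 1.24 for HMGCS1, -0.14 and 1.88 for ITGA2B, and 0.17 and 1.55 for PECAM1. In AML-193 they were -1.39 and 0.15 for SCD, and bright probe sets of MS4A3, PSPH, FCF1, SQLE, TRIB3 and HMGCS1 also had values of both signs in that line. These are not all such genes.

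All 8 groups were fitted together with limma (3.58.1, in R 4.3.3), 1 mean per group, with 8 residual and 4.80 prior degrees of freedom, empirical Bayes moderation and adjustment by Benjamini and Hochberg at 0.05. Contrasts were AZA minus vehicle in each line, the mean of the 4 differences, the 6 differences between pairs of lines, and moderated F-tests for any difference of the effects and for any difference between the vehicle groups. Sharing of calls between lines was compared with the product of their shares, with Fisher's exact test per pair. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over all lists and the 5 contrasts together, with an estimated correlation and fry as companions. The samples, comparisons, gene lists, rule for named genes and alternatives were chosen before the data were examined; the covariate and the other additions named in the closing section were not.

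The genes named are, per line, the 10 with the largest rise and the 10 with the largest fall among called genes whose 2 AZA arrays both lie above, or both below, the 2 vehicle arrays. For the mean they are the 10 and 10 among called genes with 1 sign in all lines, and for the difference between lines the 10 with the widest range. Up to 4 called members with the largest change are eligible from each list and contrast, and text space decided which of these are given. DNMT1, DNMT3A, DNMT3B, UHRF1, TET1, TET2 and TET3 are named in any case, as are values in other lines of a gene already named.

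The 37 lists were cancer-testis and germline genes, interferon-stimulated genes, double-stranded RNA and DNA sensing, MHC class I and MHC class II antigen presentation, AML surface targets, immune checkpoint ligands and receptors, integrins and adhesion molecules, CD-numbered genes, solute carriers, C2H2 zinc finger genes named ZNF, DNA methylation machinery, azacitidine uptake and metabolism, p53 target genes, apoptosis regulators, DNA replication and E2F targets, G2/M and mitosis, and MYC and ribosome biogenesis. Further lists were markers of monocytes and macrophages, granulocytes, haematopoietic stem and progenitor cells, erythroid cells and megakaryocytes, T and NK cells and B cells, epithelial genes, fibroblast and matrix genes, cholesterol biosynthesis, integrated stress response and amino acid genes, unfolded protein response, TNF and NF-kB targets, AP-1 and immediate early genes, metallothioneins and oxidative stress, histone genes, imprinted genes, HOX genes, olfactory and taste receptor genes, and housekeeping genes. They were written from general knowledge, and some genes are in several lists.

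The fit was tested on simulated data with 67, 67 and 66 of the 14049 genes changed by log2 0.5, 1 and 2. At 0.5 it recovered 83.6% in AML-193, 76.1% in HNT-34, 70.2% in KG1a, 67.2% in HL60 and 100% in the mean. At 1 it recovered 98.5% in HNT-34 and 100% in the others, and at 2 it recovered 100% in each; the share of false calls was 3.78% to 6.74%. A difference between lines of 0.5 was recovered for 22.4% to 31.3% of genes, of 1 for 97.0% to 98.5% and of 2 for 100%, with 2.65% to 9.32% false calls. A list shifted by 0.3 in KG1a was found, with 0 calls by camera among the lists that were not shifted, counted in the 4 lines without the mean. The simulated noise was independent between genes, so this does not show how often camera calls lists of correlated genes falsely. Each gene had the same simulated spread on every array, so the recoveries do not rank the lines by power.

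Alternatives were the mean of all probe sets of a gene, leaving out probe sets with shared suffixes, no filter and a stricter filter, quantile normalization again, centring on the array median, a variance trend, array weights, a stricter adjusted p, a 2-fold minimum, each line's own 4 arrays, each line as 1 replicate, and leaving out each array in turn. The 3′ minus 5′ signal of the ACTB and GAPDH controls was added as a covariate after the data were seen. Tables were read with the package data.table (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Proteome data named in the series title were not used here.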

Results

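Transcript levels were measured on 16 Affymetrix whole-genome arrays in 4 established human acute myeloid leukaemia (AML) cell lines: AML-193, a monocytic line, HNT-34, KG1a, an immature line, and HL60, a promyelocytic line. Each line received vehicle (DMSO) or 0.5 µM azacitidine (AZA), a cytidine analogue that is built into RNA and DNA and traps DNA methyltransferases, on each of 3 days and then grew without drug for 4 days. Every combination of line and treatment had 2 arrays, which makes 8 groups. The labels do not say that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The stated purpose was to follow how AZA affects the control of DNA methylation. The arrays measure transcripts, and the series title speaks of variable remodelling of cell surface proteins, so the comparisons ask which transcripts differed after AZA in each line, which did so in all lines, and where the lines differed. Changes are AZA minus vehicle on the log2 scale, ± is the standard error of the limma fit, and each line has 2 arrays per arm. For every gene named among the largest changes of a line, both AZA arrays lay on the same side of both vehicle arrays.

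The deposited values had the same distribution on every array. Replicate arrays correlated across genes at r = 0.995 to 0.998, AZA and vehicle arrays of 1 line at 0.969 to 0.989, and arrays of different lines at 0.796 to 0.910; genes are not independent replicates. Of the variance of the tested genes, 89.8% lay between lines, 8.71% between AZA and vehicle within lines, and 1.5% between replicates. The 3′ minus 5′ signal of the ACTB and GAPDH control probe sets, a measure of RNA integrity that is larger when RNA is degraded, differed between the arms of AML-193 and HL60. It was 1.27 ± 0.463 log2 units (SD, n = 2) in AML-193 with vehicle against 0.198 ± 0.0433 with AZA, and 0.0443 ± 0.0116 in HL60 with vehicle against 0.722 ± 0.163 with AZA. In HNT-34 it was -0.0033 ± 0.108 with vehicle and -0.102 ± 0.0136 with AZA, and in KG1a 0.0305 ± 0.129 and 0.0587 ± 0.00135. The difference thus ran in opposite directions in AML-193 and HL60, and a fit with this signal difference as a covariate, added after the data were seen, is given beside the results of these lines. As each group has its own mean, the slope of the covariate comes only from differences between the 2 arrays of a group. These were widest in AML-193 with vehicle (SD 0.463), then in HL60 with AZA (0.163). Values with the covariate thus extend a slope from few arrays to a larger difference between arms, and are no secure correction.

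**Figure D1:**
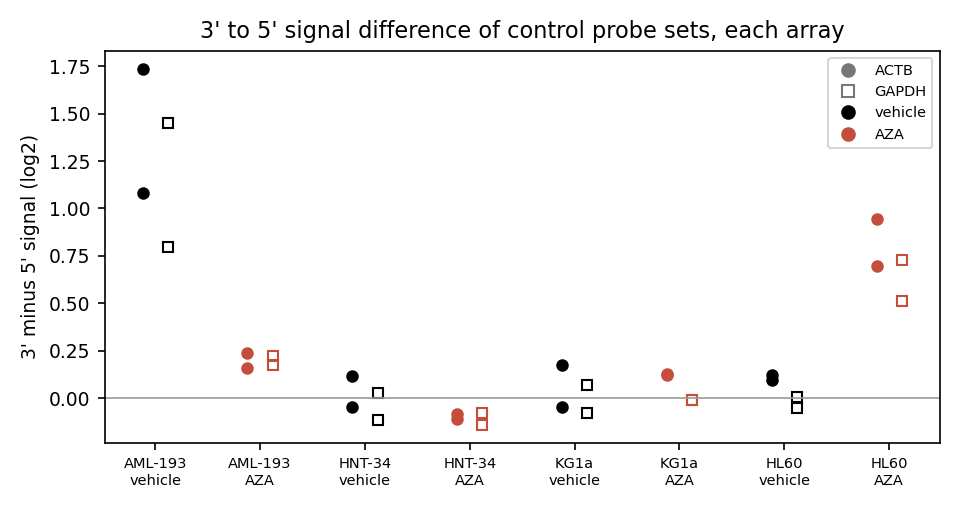
The 3′ minus 5′ signal (log2, vertical axis) of the ACTB and GAPDH control probe sets on each array, by cell line and treatment (horizontal axis), with 1 point per array for ACTB (filled) and for GAPDH (open). The AML-193 vehicle arrays, with means of 1.59 and 0.939, and the HL60 AZA arrays, with 0.837 and 0.607, lie above the others.

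With vehicle alone, 11955 of the 14049 genes tested (85.1%) differed between the 4 lines (moderated F-test, adjusted p under 0.05). The AML-193 vehicle arrays had a larger 3′ minus 5′ signal (1.27) than those of HNT-34 (-0.0033), KG1a (0.0305) and HL60 (0.0443). Part of the difference of AML-193 from the other lines cannot be told apart from it, and no count with the covariate is given here. AML-193 had the highest levels of AZU1, a neutrophil granule protein gene (log2 6.49 above the mean of the other lines), and of S100A8 (5.94), a calcium-binding protein gene of monocytes and neutrophils. HNT-34 stood out by MECOM (7.80), a transcription factor gene that is rearranged in some AML, and by CRISP3 (7.30) and ZIC2 (6.50). KG1a led in CRISPLD1 (6.95), GNG11 (6.54) and RSAD2 (6.35), an interferon-induced antiviral gene. HL60 led in ANXA5 (7.72), BASP1 (7.50) and MPO (6.67), the myeloperoxidase gene.

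In AML-193, 2907 genes were higher and 2844 lower after AZA, 5751 of 14049 in all, and 280 of the higher and 146 of the lower changed at least 2-fold. The largest rises were in FABP4, a fatty acid carrier of adipocytes and macrophages (5.41 ± 0.09), the platelet chemokine gene PPBP (4.86 ± 0.19), the germline gene GTSF1 (4.75 ± 0.10), S100P (4.22 ± 0.09) and SPP1, which encodes osteopontin (3.76 ± 0.15). The neutrophil elastase gene ELANE (3.67 ± 0.22), DCAF4L1 (3.60 ± 0.13), the monocyte chemoattractant gene CCL7 (3.25 ± 0.11), S100A12 (3.23 ± 0.12) and the mannose receptor gene MRC1 (3.13 ± 0.11) followed. The largest falls were in CTH, the cystathionine cleaving enzyme of cysteine synthesis (-3.04 ± 0.09), the asparagine synthetase gene ASNS (-2.59 ± 0.10), OLMALINC (-2.44 ± 0.15), CHRM3-AS2 (-2.38 ± 0.09) and TUBE1 (-2.09 ± 0.12). CBS, which acts ahead of CTH in the same pathway (-1.83 ± 0.07), the receptor gene CD96 (-1.73 ± 0.09), the mitochondrial enzyme gene PCK2 (-1.70 ± 0.09), RUNDC3B (-1.70 ± 0.12) and the glutathione-cleaving enzyme gene CHAC1 (-1.68 ± 0.11) fell as well. The adjusted p of these 20 genes was at most 6.96e-07. With the 3′ to 5′ covariate the number of genes called fell to 373, of which 329 were called without it in the same direction. The 20 genes named kept their calls, and 4933 of the 5751 kept their sign.

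Among marker lists of blood cells, 31 of 42 monocyte and macrophage genes rose in AML-193, 1 fell and 10 did not pass (list median 0.83; camera adjusted p = 4.16e-11, and 0.0116 with an estimated correlation). S100A12, MRC1, the scavenger receptor gene CD36 (2.72 ± 0.15) and FCER1G, an Fc receptor chain (2.18 ± 0.14), led, and 31 rose and 2 fell when adjusted over the list alone. Probe sets of CD36 ranged from -0.04 to 3.20 in this line, and none had a mean signal over its arrays as high as the array median. Of 37 granulocyte genes 17 rose and 6 fell, with the same counts adjusted over the list alone, including MPO (3.11 ± 0.14) and the formyl peptide receptor gene FPR2 (2.45 ± 0.15). The list was called at 0.00112, but its adjusted p was 0.0769 with an estimated correlation. The vehicle arrays of this line had the larger 3′ minus 5′ signal (1.27 against 0.198), and with the covariate 9 monocyte genes rose and none of them fell, while 6 granulocyte genes rose and 1 fell. The list medians were then 0.48 and 0.21, and both lists kept their call (1.3e-08 and 0.00378).

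Lists of surface proteins named as AML targets and of CD-numbered genes shifted upwards in AML-193, while integrins and adhesion molecules (adjusted p = 0.068, but 0.00419 with averaged probe sets and 0.0461 without the filter), checkpoint genes (0.149), solute carriers (0.696) and MHC class I (0.789) and class II genes (0.836) were not called there. Of 44 surface proteins named as AML targets, 22 rose and 6 fell (median 0.25, adjusted p = 0.00112, 0.0246 with an estimated correlation), and of 64 CD-numbered genes 32 rose and 5 fell (0.21, 0.000118, 0.0286). Both pairs of counts were the same adjusted over the list alone. CD52, the target of alemtuzumab (2.26 ± 0.27), and CD14, a co-receptor for bacterial lipopolysaccharide (1.65 ± 0.17), rose beside CD36, and CD96 fell. With the covariate the medians were 0.19 and 0.28 and both lists kept their call (0.00088 and 3.23e-05), with 7 genes higher and 1 lower in each. CD52 was then at 3.99, and CD14 no longer passed, at a similar log2 change (1.61) with a wider error.

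Of 34 genes induced by ATF4 in the integrated stress response or serving amino acid synthesis and uptake, 27 fell in AML-193 and 2 rose (median -1.04, adjusted p = 3.4e-16, 0.00167 with an estimated correlation; 27 and 4 adjusted over the list alone). With the covariate the list median was -0.79, 19 members fell and the list kept its call (6.42e-26). Cholesterol synthesis genes fell in 12 of 22 members and rose in 1, with the same counts over the list alone (median -0.43, 6.67e-05, 0.0338 with an estimated correlation), led by the regulator SREBF1 (-1.62 ± 0.11), the desaturase gene SCD (-1.39 ± 0.11) and MSMO1 (-0.99 ± 0.08). With the covariate the median was -0.62 and the adjusted p of the list 1.81e-08, while 4 members still passed. The 413 tested C2H2 zinc finger genes named ZNF fell in 132 members and rose in 40 (median -0.11, 0.0019, 0.0338 with an estimated correlation; 1 more of each over the list alone), and with the covariate the median was -0.09 and the list p 0.00878, while 3 members passed as lower and 2 as higher.

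Several lists were called by camera in AML-193 with the preset correlation but not with an estimated one. Targets of TNF and NF-kB rose in 18 of 36 members and fell in 5 (19 and 5 over the list alone; 0.0019, but adjusted p = 0.0983 with an estimated correlation), including IER3 (2.20 ± 0.09), the interleukin-1β gene IL1B (2.10 ± 0.09) and CCL2 (1.93 ± 0.15). Metallothionein and oxidative stress genes rose in 15 of 27 and fell in 1 (16 and 2; 0.000125, 0.0614 with an estimated correlation), with the haem oxygenase gene HMOX1 at 1.83 ± 0.15 and NQO1 at 1.36 ± 0.10. Unfolded protein response genes rose in 14 of 23 and fell in 1 (14 and 3; 0.00165, 0.115 with an estimated correlation), and with the covariate the list test gave an adjusted p of 0.178. Of 26 cancer-testis and germline genes 12 rose and 1 fell (12 and 1; 0.0019, 0.109 with an estimated correlation), led by GTSF1 and MAGEB2 (2.64 ± 0.24), and the adjusted p was 0.0584 with the covariate. Replication and E2F target genes fell in 20 of 47 and rose in 8 (20 and 9; 0.0246, 0.064 with an estimated correlation), and the adjusted p was 0.756 when probe sets of a gene were averaged and 0.0634 without vehicle array 2. Interferon-stimulated genes fell in 19 of 62 and rose in 3 (18 and 3; 0.0379, 0.067), with 0.112 without vehicle array 2 and 0.0513 without AZA array 2. DNA methylation machinery genes fell in 11 of 23 and rose in 1 (11 and 1; 0.00843, 0.064). With the covariate 3 genes of the metallothionein list rose and 1 fell, and 4 TNF targets, 1 unfolded protein response gene and 2 cancer-testis genes rose. Of the other lists 1 replication gene and 1 methylation gene fell, and 3 interferon-stimulated genes fell and 1 rose. The list tests kept their calls with the covariate for TNF targets (0.00918), metallothioneins (0.0181), replication genes (0.0115), interferon-stimulated genes (0.0198) and methylation machinery (0.0222), and fibroblast genes gained one (0.0398 against 0.0805). The list medians with it were -0.11 against -0.21 for methylation machinery, -0.12 against -0.18 for replication genes and 0.20 against 0.37 for the unfolded protein response.

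In HNT-34, 2165 genes were higher and 2080 lower after AZA, 4245 in all, with 318 and 166 changed at least 2-fold. ZNF595, a zinc finger gene, rose most (6.47 ± 0.12), followed by PPBP (5.56 ± 0.19), the cancer-testis antigen gene MAGEA4 (5.21 ± 0.12), the thrombin receptor gene F2RL2 (4.93 ± 0.16), SLITRK6 (4.83 ± 0.13) and GJA1, which encodes the gap junction protein connexin 43 (4.82 ± 0.15). The germ cell gene GCNA (3.98 ± 0.13), AKAP12 (3.96 ± 0.15), the immediate early gene EGR3 (3.90 ± 0.17) and HGD, an enzyme of tyrosine breakdown (3.88 ± 0.08), completed the 10. The falls were led by the secreted factor gene INHBE (-3.67 ± 0.13), the cystine importer gene SLC7A11 (-3.17 ± 0.10), KIAA0087 (-3.02 ± 0.12), CHAC1 (-2.91 ± 0.11) and the cathepsin G gene CTSG (-2.79 ± 0.09). PHGDH, the first enzyme of serine synthesis (-2.66 ± 0.13), TRIB3, an inhibitor of ATF4 (-2.51 ± 0.10), the β-glucan receptor gene CLEC7A (-2.39 ± 0.14), the tryptophanyl-tRNA synthetase gene WARS1 (-2.36 ± 0.07) and PCK2 (-2.26 ± 0.09) also fell. The adjusted p of these 20 genes was at most 4.65e-08. A second probe set of ZNF595 gave a smaller rise of 1.24 in this line.

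The ATF4 and amino acid list fell in 27 of 34 members and rose in none (median -1.24, adjusted p = 1.04e-22, 0.000633 with an estimated correlation, and the same counts over the list alone). Of 22 cholesterol synthesis genes 15 rose and 1 fell (median 0.60, 1.41e-06, 0.0175 with an estimated correlation; 16 and 2 over the list alone). HMGCS1 (1.53 ± 0.09), SQLE (1.29 ± 0.23) and the sterol sensor partner gene INSIG1 (1.22 ± 0.09) led these rises. Erythroid and megakaryocyte genes rose in 21 of 37 members and fell in 1, also over the list alone (median 0.52, 2.22e-08, 0.0197 with an estimated correlation). They included RHAG, a red cell ammonium channel (3.72 ± 0.15), the transcription factor gene GATA1 (2.34 ± 0.08) and the δ-globin gene HBD (1.87 ± 0.10). T and NK cell genes rose in 19 of 37 and fell in 1, also over the list alone (0.29, 8.97e-05, 0.0369), with the adaptor gene LAT at 3.61 ± 0.08 and the perforin gene PRF1 at 1.73 ± 0.12. Cancer-testis genes rose in 12 of 26, and none fell, adjusted either way (0.35, 3.11e-06, 0.0369), including MAGEB2 (3.02 ± 0.24), MAGEA6 (2.84 ± 0.17) and MAGEA1 (2.68 ± 0.13). Replication and E2F targets fell in 24 of 47 and rose in 3 (-0.24, 2.25e-05, 0.0116; 25 and 3 over the list alone), among them UHRF1, which guides DNA methylation to copied DNA (-0.85 ± 0.08), and the helicase subunit genes MCM5 (-0.73 ± 0.08) and MCM3 (-0.69 ± 0.06). Interferon-stimulated genes rose in 24 of 62 and fell in 9 (0.15, 0.00797, 0.035; 25 and 9 over the list alone), including IFI27 (1.90 ± 0.13) and ISG15 (1.63 ± 0.08).

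The other called lists of HNT-34 lost their call with an estimated correlation. Mitosis genes rose in 16 of 46 and fell in 1, also over the list alone (0.0019, adjusted p = 0.0895 with an estimated correlation). Histone genes rose in 11 of 25 and fell in 1 (4.18e-05, 0.0835; 14 and 1 over the list alone), with H2BC5 at 1.83 ± 0.15. MYC and ribosome biogenesis genes fell in 10 of 38 and rose in 3 (0.000756, 0.0706; 14 and 3). Targets of p53 rose in 11 of 35 and fell in 4 (0.038, 0.0846; 13 and 4), including CDKN1A, the p21 gene (1.08 ± 0.14), while SESN2, which ATF4 also induces, fell (-1.44 ± 0.09). AML surface targets fell in 18 of 44 and rose in 11, also over the list alone (median -0.12, 0.0397, 0.0803), with the adhesion molecule gene NCAM1 at -1.96 ± 0.14, the CD30 gene TNFRSF8 at -1.98 ± 0.15 and SIGLEC6 at 2.22 ± 0.11. Fibroblast and matrix genes rose in 8 of 27, and none fell, adjusted either way (0.0355, 0.294), among them S100A6 (3.06 ± 0.16) and LOXL1 (1.71 ± 0.14), the first of which is also made by blood cells. The median of this list depends on the scaling: it was 0.07, and 0.005 after quantile normalization again. The p53 list had an adjusted p of 0.0899 without HNT-34 vehicle array 1, 0.0662 without AZA array 1 and 0.0623 with averaged probe sets. The surface target list had 0.0588 and 0.0618 without AML-193 vehicle arrays 1 and 2, 0.0507 without HL60 AZA array 2, 0.0511 with averaged probe sets and 0.0584 with the covariate. The fibroblast list had 0.0676 without HNT-34 AZA array 1 and 0.142 without the filter on dim genes.

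In KG1a fewer genes passed, 921 higher and 472 lower, 1393 in all, with 132 and 10 changed at least 2-fold. The largest rises were in the collagen gene COL14A1 (6.77 ± 0.15), the eosinophil major basic protein gene PRG2 (5.96 ± 0.07), CLC, which forms Charcot-Leyden crystals (4.42 ± 0.18), ZNF595 (3.44 ± 0.12), the histamine-forming enzyme gene HDC (3.43 ± 0.09) and MS4A3 (3.39 ± 0.08). The vitamin B12 carrier gene TCN1 (3.04 ± 0.15), the cholesterol transporter gene STAR (3.02 ± 0.19), the transcription factor gene CREB5 (2.93 ± 0.13) and the nuclear receptor gene NR5A2 (2.70 ± 0.17) completed the 10. A second probe set of ZNF595 was at -0.41 here and another of COL14A1 at 0.84. The falls were smaller and were led by RBPMS (-1.52 ± 0.12), the endothelial sialomucin gene EMCN (-1.40 ± 0.13), KIAA0087 (-1.32 ± 0.12), COL24A1 (-1.17 ± 0.15) and the chemokine receptor gene CCR9 (-1.17 ± 0.15). C6orf141 (-1.15 ± 0.09), SETBP1 (-1.08 ± 0.17), PSAT1, an enzyme of serine synthesis (-1.07 ± 0.18), the BMP inhibitor gene NOG (-1.07 ± 0.13) and SHANK2 (-1.03 ± 0.09) fell as well. No probe set of RBPMS, EMCN, NR5A2 or ZNF595 had a mean signal over the arrays of this line as high as the array median. Probe sets ranged from -1.52 to -0.03 for RBPMS, from -1.40 to -0.38 for EMCN and from 0.02 to 3.49 for NR5A2. The adjusted p of the 20 genes was at most 0.00186. With each array centred on its median 789 were higher and 622 lower. The count depends on single arrays: it was 877 without vehicle array 1, 698 without AZA array 1 and 688 without AZA array 2, and 844 on the 4 arrays of this line alone.

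Granulocyte genes rose in 14 of 37 members in KG1a, and none fell (median 0.25, adjusted p = 4.25e-08, 0.0172 with an estimated correlation; 16 rose over the list alone), including RNASE2, an eosinophil ribonuclease (1.81 ± 0.15). Monocyte and macrophage genes rose in 14 of 42 and fell in 1 (0.16, 3.31e-06, 0.0348; 17 and 1 over the list alone), with the adaptor gene TYROBP at 2.14 ± 0.08 and CD86 at 1.34 ± 0.13. T and NK cell genes rose in 17 of 37 and fell in 3 (0.38, 9.62e-09, 0.0116; 24 and 3 over the list alone), led by the T cell receptor chain gene CD3D (2.13 ± 0.08), KLRB1 (1.84 ± 0.14) and the granzyme gene GZMA (1.29 ± 0.09). Unfolded protein response genes rose in 8 of 23, and none fell (0.24, 8.89e-06, 0.0488; 13 rose over the list alone). The ATF4 and amino acid list fell in 15 of 34 and rose in 3 (-0.19, 3.11e-06, 0.0172; 16 and 4 over the list alone). Replication and E2F targets shifted down (-0.13, 1.01e-05, 0.011) with 3 of 47 members called, RFC5 (-0.41 ± 0.12), CDC45 (-0.22 ± 0.06) and DTL (-0.20 ± 0.06), and 0 over the list alone. These 3 calls were lost in most omissions of 1 array.

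The remaining called lists of KG1a lost their call with an estimated correlation. Erythroid and megakaryocyte genes rose in 8 of 37 and fell in 3 (0.000524, adjusted p = 0.0776 with an estimated correlation; 11 and 3 over the list alone), including the integrin gene ITGA2B (1.92 ± 0.13) and GATA1 (1.64 ± 0.08). CD-numbered genes rose in 14 of 64 and fell in 3 (0.00958, 0.0776; 19 and 5). Cancer-testis genes rose in 5 of 26 adjusted either way (0.0133, 0.176), with GTSF1 at 2.46 ± 0.10 and TDRD9 at 1.40 ± 0.15. Fibroblast and matrix genes rose in 6 of 27 (0.00404, 0.17; 7 over the list alone), with VIM, the vimentin gene that leukocytes also express, at 1.55 ± 0.14. TNF and NF-kB targets rose in 7 of 36 (0.0246, 0.202; 10 rose and 1 fell over the list alone), with the prostaglandin synthase gene PTGS2 at 1.29 ± 0.18. Without the filter on dim genes the cancer-testis list had an adjusted p of 0.118 and the fibroblast list 0.0766 in this line. Without KG1a vehicle array 1 they had 0.149 and 0.0876, and the TNF list had 0.241 without vehicle array 2 and 0.116 without AZA array 2. The small medians here depend on the scaling: after quantile normalization again they were 0.03 for cancer-testis genes, 0.03 for CD-numbered genes and 0.01 for fibroblast genes. Integrins were not called in KG1a (0.0623) but were with averaged probe sets (0.012) and without the filter (0.0489), as were surface targets without the filter (0.0471 against 0.0965).

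In HL60, 3541 genes were higher and 2252 lower after AZA, 5793 in all, with 305 and 185 changed at least 2-fold. The excess of rises over falls depends on the scaling and on the choice of probe set. With each array centred on the median of its tested genes, 2565 were higher and 3165 lower. With the probe sets of a gene averaged, 2703 were higher and 2719 lower. The largest rises were CLC (6.60 ± 0.18), ZNF595 (6.42 ± 0.12), the transketolase-like gene TKTL1 (6.11 ± 0.16), the eosinophil peroxidase gene EPX (5.83 ± 0.15), COL14A1 (4.88 ± 0.15) and DCAF4L1 (4.55 ± 0.13). GCNA (4.07 ± 0.13), CD93, a receptor of myeloid and endothelial cells (3.84 ± 0.08), S100A6 (3.77 ± 0.16) and the cation channel gene TRPM4 (3.71 ± 0.19) followed. The largest falls were PSAT1 (-3.61 ± 0.18), PSPH, the last enzyme of serine synthesis (-2.69 ± 0.28), FCF1 (-2.61 ± 0.35), INHBE (-2.51 ± 0.13), AJUBA (-2.43 ± 0.15), GTF2I (-2.26 ± 0.35) and the argininosuccinate synthetase gene ASS1 (-2.25 ± 0.12). The ATP receptor gene P2RX7 (-2.12 ± 0.16), the glycoprotein hormone gene STC2 (-2.11 ± 0.08) and CHRM3-AS2 (-2.07 ± 0.09) fell as well. The adjusted p of the 20 genes was at most 0.000269. Other probe sets in this line gave 0.10 for PSPH, up to 0.42 for FCF1, 0.89 for CD93, -0.07 for S100A6 and -0.11 for AJUBA, and down to -0.01 for COL14A1. With the 3′ to 5′ covariate 2149 genes were called, 1940 of them among the 5793. Of the 20 genes GTF2I lost its call (-1.43), and FCF1 kept it at -1.55.

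The granulocyte list rose in 21 of 37 members in HL60 and fell in 3, also over the list alone (median 0.44, adjusted p = 6.29e-05, 0.0419 with an estimated correlation), with the proteinase 3 gene PRTN3 at 2.94 ± 0.14 and ELANE at 2.78 ± 0.22 beside CLC and EPX. The AZA arrays had the larger 3′ minus 5′ signal in this line (0.722 against 0.0443), and with the covariate 16 rose and 2 fell. The ATF4 and amino acid list fell in 31 of 34, and none rose, adjusted either way (median -0.87, 1.04e-22, 0.000633 with an estimated correlation). With the covariate 27 fell. Integrins and adhesion molecules rose in 16 of 46 and fell in 3, also over the list alone (0.11, 0.0135, 0.0488), including the CD11b gene ITGAM (2.22 ± 0.08), ITGA2B (1.80 ± 0.13) and PECAM1 (1.55 ± 0.09). A second, dimmer probe set of ITGAM gave -0.37. The median of this list was 0.02 with each array centred on its median and 0.07 after quantile normalization again, but 0.20 with the covariate. In it 15 rose and 1 fell with the covariate, and the adjusted p was 0.0661 when probe sets of a gene were averaged. Monocyte and macrophage genes rose in 22 of 42 and fell in 4 (0.00183, adjusted p = 0.096 with an estimated correlation; 23 and 4 over the list alone; 17 and 1 with the covariate, and a median of 0.49 with it against 0.32), including S100A12 (2.66 ± 0.12) and S100A8 (1.99 ± 0.19). Cancer-testis genes rose in 14 of 26 and fell in 2, also over the list alone (0.00618, 0.14; 8 rose with the covariate), led by TKTL1, MAGEB2 (3.33 ± 0.24) and MAEL (2.88 ± 0.13). Cholesterol synthesis genes rose in 14 of 22 and fell in 1, also over the list alone (0.00555, 0.0846; 7 rose with the covariate), with HMGCS1 at 1.24 ± 0.09 and its second bright probe set at -0.20. The adjusted p of this list was 0.0918 without HL60 AZA array 2. Mitosis genes rose in 25 of 46 and fell in 4 (0.00301, 0.0962; 28 and 4 over the list alone; 8 and 1 with the covariate), and the adjusted p was 0.192 when probe sets of a gene were averaged. Some lists that were not called in HL60 were called with the covariate: metallothioneins (0.00169 against 0.074), unfolded protein response (0.0092 against 0.198), interferon-stimulated genes (0.0167 against 0.136) and replication genes (0.0353 against 0.0657). With averaged probe sets metallothioneins (0.00524), interferon-stimulated genes (0.0321), replication genes (0.0088) and fibroblast genes (0.00419) were called there, and without the filter interferon-stimulated genes (0.0341) and metallothioneins (0.0498).

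**Figure D2:**
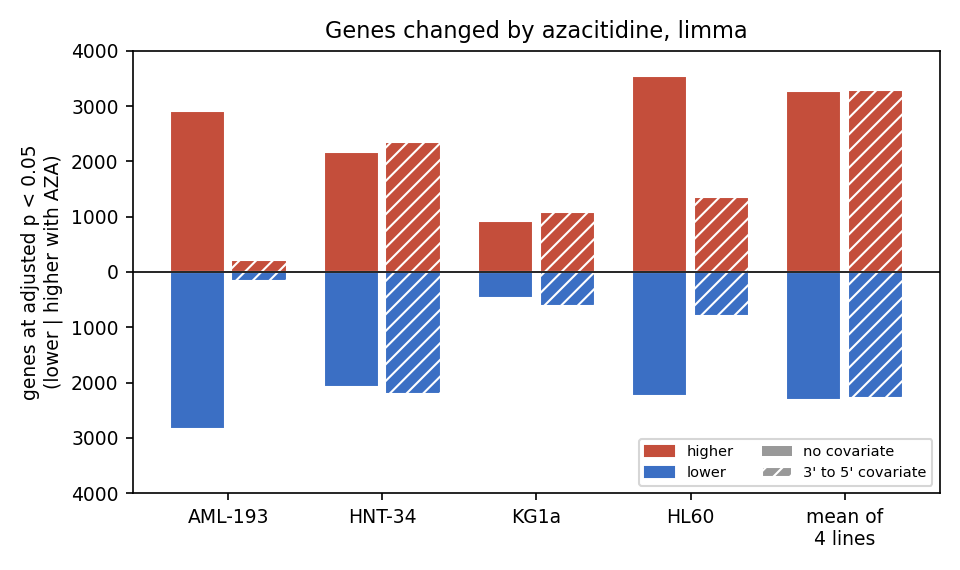
Number of genes (vertical axis) higher (upward bars) or lower (downward bars) after AZA at limma-adjusted p under 0.05, in each line and on average over the 4 lines, without (plain) and with (hatched) the 3′ to 5′ signal difference as a covariate. The count fell from 5751 to 373 in AML-193 and from 5793 to 2149 in HL60, and was 4245 and 4556 in HNT-34.

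Averaged over the 4 lines, 3277 genes were higher and 2321 lower after AZA, 5598 in all, and 89 and 15 changed at least 2-fold. The mean speaks of these lines only: with each line counted as 1 replicate limma called 0 genes, and 1235 genes had an unadjusted p under 0.05. With each array centred on its median, 2613 were higher and 2964 lower. Among genes with 1 sign in all lines, the largest mean rises were ZNF595 (4.13 ± 0.06), COL14A1 (3.67 ± 0.08), PPBP (3.23 ± 0.10), GCNA (2.99 ± 0.06), CLC (2.85 ± 0.09), TRPM4 (2.65 ± 0.09), DCAF4L1 (2.62 ± 0.06), MAGEB2 (2.55 ± 0.12), the globin regulator gene NFE4 (2.26 ± 0.08) and CREB5 (2.08 ± 0.07). CLC was not called in AML-193 (0.13) and HNT-34 (0.27), ZNF595 not in AML-193 (0.20), and the AML-193 call of COL14A1 (0.50) gave -0.08 with the covariate. With it CLC was at 1.12 in AML-193 and called in HNT-34 (0.36), and ZNF595 was at 0.50 in AML-193. The largest mean falls were CHAC1 (-1.88 ± 0.05), SLC7A11 (-1.78 ± 0.05), INHBE (-1.73 ± 0.07), CHRM3-AS2 (-1.69 ± 0.05), ASNS (-1.62 ± 0.05), CBS (-1.52 ± 0.03), PCK2 (-1.38 ± 0.04), TUBE1 (-1.25 ± 0.06), WARS1 (-1.24 ± 0.04) and TMEM268 (-1.14 ± 0.04), at adjusted p of at most 5.47e-09.

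**Figure D3:**
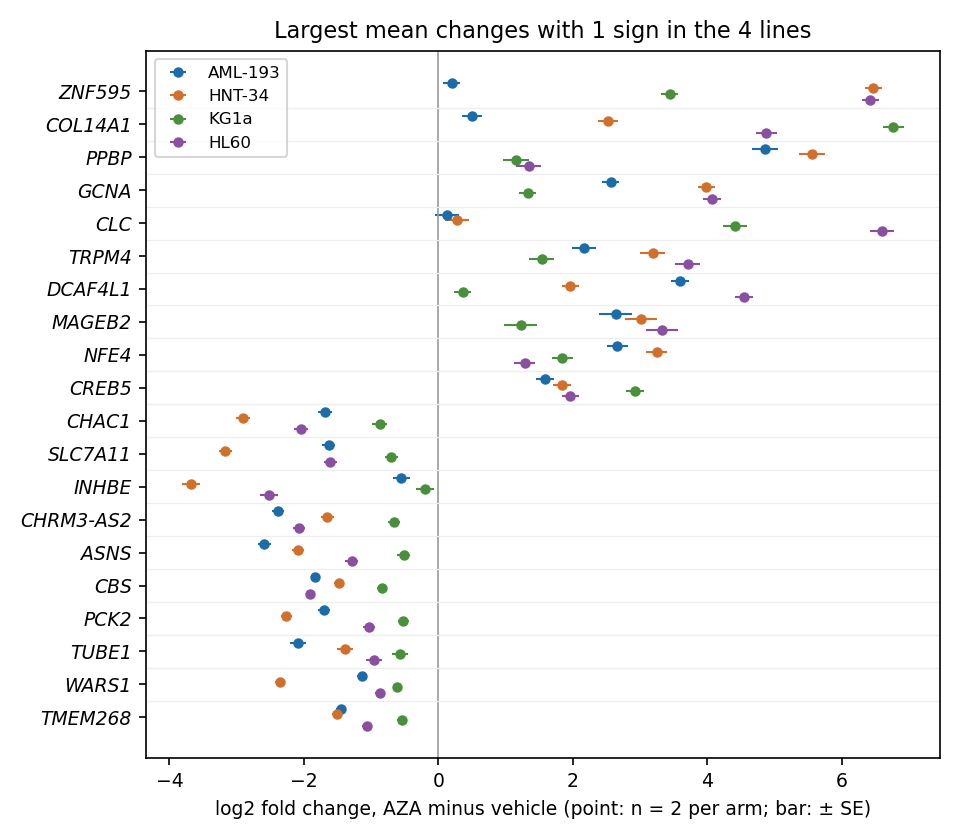
Log2 fold change (AZA minus vehicle, horizontal axis) in each line of the 10 genes with the largest mean rise and the 10 with the largest mean fall among genes with 1 sign in the 4 lines, with bars of ± 1 SE and 2 arrays per arm. ZNF595 ranged from 0.20 in AML-193 to 6.47 in HNT-34, and the small rise of COL14A1 in AML-193 turns to -0.08 with the 3′ to 5′ covariate.

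Across lines, 9928 genes were called in at least 1 line, 4645 in 1 line alone and 2840 in both directions in different lines. With the covariate these counts were 6243, 4248 and 516. In all 4 lines 100 genes rose, where independent calls would give 7.4, and 45 fell, where they would give 2.27. The lines share no control arrays, but the fit uses 1 estimate of the spread per gene for all groups. A gene of small spread is thus more readily called in every line, so calls are not independent and these numbers are only a reference. The same limit holds for the pairs of lines and their Fisher's exact test, since genes are not independent either. With the covariate 39 genes were called in 1 direction in all 4 lines, against 145 without it, and the count was 91 without KG1a AZA array 1 and 93 without KG1a AZA array 2. At 2-fold or more in each line 7 genes rose and 0 fell. Genes that rose in all lines included PPBP, GCNA, TRPM4, MAGEB2, NFE4, CREB5, LGALS3BP, a secreted glycoprotein induced by interferon (mean 2.00 ± 0.04), TYROBP (mean 1.90 ± 0.04) and the growth factor gene CLEC11A (mean 1.72 ± 0.05). In the ATF4 and amino acid list 12 of 34 genes fell in all 4 lines and 24 in 3 or more, among them CHAC1, SLC7A11, ASNS, CBS, PCK2 and WARS1. Relative to independent calls HNT-34 and KG1a shared most, with 449 genes higher in both (141.9 for independent calls, Fisher's exact test p = 1.52e-136) and r = 0.39 between their fold changes across genes. AML-193 and HL60 shared fewer than independent calls would give, 563 higher in both (732.7) and 348 lower in both (455.9). In opposite directions 2025 genes were called (1183), and r was -0.11, with a Spearman rank correlation of -0.24. These 2 lines are those whose 3′ minus 5′ signal differed in opposite directions.

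Of the gene lists, 33 of the 34 ATF4 and amino acid genes fell in the mean over the lines and none rose, adjusted either way (median -0.79, adjusted p = 8.24e-34, 0.000402 with an estimated correlation). Granulocyte genes rose in 27 of 37 and fell in 2 (0.33, 1.17e-09, 0.0116), and monocyte and macrophage genes in 30 of 42 with 2 falls (0.39, 1.17e-09, 0.0158; 30 and 3 over the list alone). Cancer-testis genes rose in 18 of 26, and none fell (0.34, 2.37e-07, 0.0307; 19 rose over the list alone). Erythroid and megakaryocyte genes rose in 21 of 37 and fell in 1 (1.49e-05, 0.0419; 22 and 1), and T and NK cell genes rose in 22 of 37 and fell in 3 (6.22e-05, 0.035; 25 and 3). CD-numbered genes rose in 33 of 64 and fell in 6 (0.000256, 0.0333; 35 and 8), with CD86 at 0.98 ± 0.07 and CD52 at 1.18 ± 0.14. Integrins and adhesion molecules rose in 19 of 46 and fell in 4, adjusted either way (0.0119, 0.0477). Replication and E2F targets fell in 29 of 47 and rose in 1 (-0.14, 3.8e-08, 0.00328; 30 and 1). Called by camera with the preset correlation but not with an estimated one were the rises of matrix genes (0.00113, adjusted p = 0.123 with an estimated correlation), where 12 of 27 rose adjusted either way. So were those of unfolded protein response genes (0.00165, 0.115; 15 of 23 rose and 4 fell, 17 and 4 over the list alone) and TNF targets (0.0144, 0.173; 20 of 36 and 2, 21 and 4). The same held for oxidative stress genes (0.000436, 0.0756; 16 of 27 and 2, 18 and 2), mitosis genes (0.038, 0.209; 18 of 46 and 1, 19 and 1) and histone genes (0.0375, 0.32; 11 of 25 and 4, 12 and 4). The mitosis list had adjusted p from 0.0519 to 0.0737 without AML-193 vehicle array 2, HNT-34 vehicle array 1, KG1a vehicle array 2 or HL60 AZA array 2, and 0.0594 with averaged probe sets. The histone list had 0.0551 without AML-193 vehicle array 2, 0.0519 without HNT-34 vehicle array 2 and 0.312 without the filter.

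**Figure D4:**
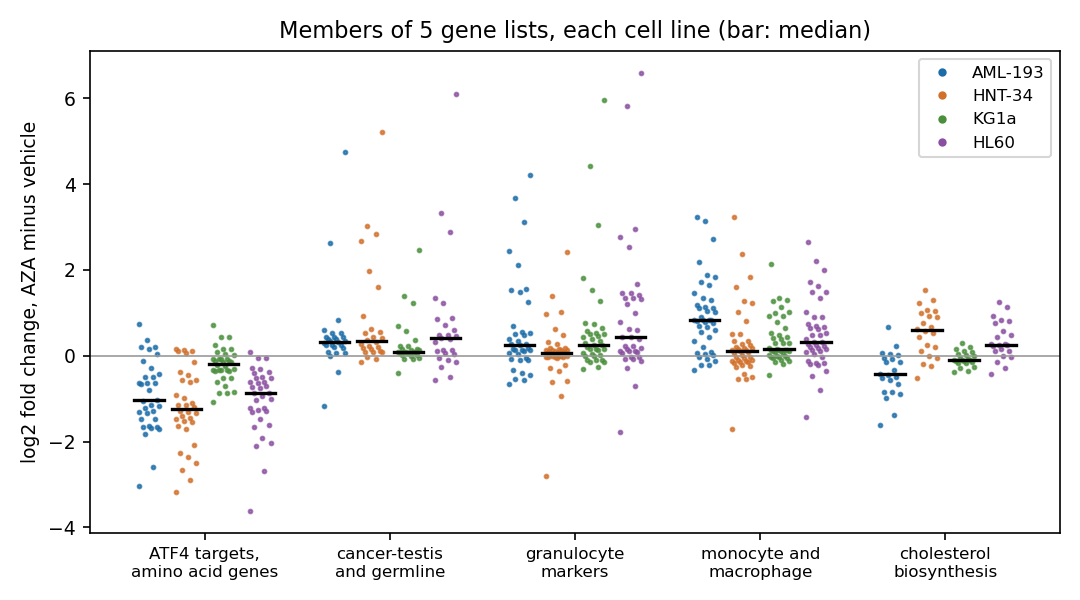
Log2 fold change (AZA minus vehicle, vertical axis) of each tested member of 5 gene lists in each line, with 1 point per gene and the list median as a bar. The ATF4 and amino acid list has medians of -1.04, -1.24, -0.19 and -0.87 in AML-193, HNT-34, KG1a and HL60, and the cholesterol list has -0.43 in AML-193 and 0.60 in HNT-34.

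Of the genes that write, copy or remove DNA methylation, DNMT1, the target of AZA, fell in HNT-34 (-0.46 ± 0.10) and in the mean (-0.24 ± 0.05), with values of -0.21 in AML-193, -0.13 in KG1a and -0.18 in HL60 that did not pass. With the covariate DNMT1 was at -0.38 in AML-193 and -0.07 in HL60. DNMT3A did not pass in any line (-0.17 to 0.13), and its AML-193 value was 0.08 with the covariate. Other probe sets of DNMT3A reached 0.72 in HNT-34, and 1 of TET3 was at 0.04 there. DNMT3B fell in AML-193 (-1.23 ± 0.12) and rose in HL60 (0.36 ± 0.12), and UHRF1 fell in AML-193 (-0.22 ± 0.08) and HNT-34 and rose in HL60 (0.41 ± 0.08). These AML-193 and HL60 calls were lost with the covariate, at -0.69 and 0.021 for DNMT3B and -0.15 and 0.37 for UHRF1. TET2, which oxidises methylated cytosine, rose in AML-193 (1.09 ± 0.15), HNT-34 (0.53 ± 0.15) and HL60 (0.75 ± 0.15), and with the covariate its AML-193 call was lost (0.26) and its HL60 value was 1.28. The lowest values among TET2 probe sets were 0.11 in AML-193, 0.20 in HNT-34 and 0.62 in HL60. In AML-193 no TET2 probe set had a mean signal as high as the array median. TET1 fell in HNT-34 (-0.41 ± 0.11) and KG1a (-0.45 ± 0.11), and TET3 fell in HNT-34 (-0.56 ± 0.11). The calls of TET1, and that of TET2 in HNT-34, were lost when single arrays of these lines were left out. APOBEC3B, a cytidine deaminase gene counted in the same list, rose in HNT-34 (2.19 ± 0.09) and KG1a (1.88 ± 0.09).

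The effect of AZA differed between the lines in 8010 of 14049 genes (57.0%; moderated F-test), and in 4401 with the covariate. Between pairs of lines 4421 genes differed for AML-193 and HNT-34, 3423 for AML-193 and KG1a, 6639 for AML-193 and HL60, 2130 for HNT-34 and KG1a, 5025 for HNT-34 and HL60, and 3787 for KG1a and HL60. The covariate lowered these to 1321, 349 and 192 for the pairs with AML-193 in that order, and to 2276 and 1524 for the other 2 pairs with HL60. The widest ranges of fold change belonged to CLC, from 0.13 in AML-193 to 6.60 in HL60, and to COL14A1, ZNF595, PRG2, GJA1, TKTL1, EPX, FABP4, F2RL2 and MAGEA4. GJA1 fell in AML-193 (-1.16 ± 0.15, and -1.77 with the covariate) and rose in HNT-34 and KG1a (1.39 ± 0.15), and PRG2 was at -0.05 in AML-193 against 5.96 in KG1a. The AZA effect on cholesterol synthesis genes was lower in AML-193 than in HNT-34, by a median of -1.03. The ATF4 and amino acid list fell less in KG1a than in AML-193, HNT-34 and HL60 (median differences of -0.87 and -0.99 for the first 2 minus KG1a and 0.66 for KG1a minus HL60). Of 222 tests of list differences between pairs of lines 37 were called, and 8 of these held with an estimated correlation.

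For 15 lists no shift was called in any of the 5 contrasts, though other settings called some. Fry, which does not compare a list with the other genes, called most of these lists in at least 1 contrast, such as housekeeping genes in the mean (2.1e-07). With averaged probe sets these were MHC class II genes in KG1a (0.00583), azacitidine uptake in HL60 (0.00647) and housekeeping genes in AML-193 (0.0418). Without the filter stem and progenitor genes were called in HNT-34 (0.0461), and with the covariate olfactory and taste receptor genes in AML-193 (0.0475). In some omissions of 1 array B cell genes were called in AML-193 (lowest 0.0141) and MHC class II genes in KG1a (0.0488). In the mean over the lines, nucleic acid sensors rose in 4 of 20 and fell in 4 (smallest adjusted p over the contrasts 0.326), MHC class I genes rose in 9 of 23 and fell in 3 (0.319). MHC class II genes rose in 1 of 16 and fell in 2 (0.0962). Checkpoint ligands and receptors rose in 12 of 27 and fell in 6 (0.149). Solute carriers rose in 77 of 269 and fell in 43 (0.345), and genes of azacitidine uptake and metabolism rose in 3 of 18 and fell in 4 (0.412). Apoptosis regulators rose in 12 of 37 and fell in 9 (0.469), stem and progenitor genes rose in 6 of 36 and fell in 9 (0.0988). AP-1 and immediate early genes rose in 14 of 35 and fell in 7 (0.203), and imprinted genes rose in 6 of 21 and fell in 3 (0.933). B cell genes rose in 7 of 24 and fell in 3 (0.0643), epithelial genes rose in 11 of 27 and fell in 3 (0.28). HOX genes rose in 4 of 16 and fell in 1 (0.717), olfactory and taste receptor genes rose in 3 of 28 and fell in 1 (0.216), and housekeeping genes rose in 9 of 24 and fell in 4 (0.13). Single members still moved, such as the nucleoside importer gene SLC29A1, which carries AZA into cells, in AML-193 (1.43 ± 0.22), and the cytidine deaminase gene CDA, which breaks AZA down, in HNT-34 (-1.44 ± 0.21). SLC29A1 lost its AML-193 call with the covariate (1.20). Adjusted over the list alone the counts in the mean were 4 and 4, 9 and 3, 0 and 1, 14 and 8, 78 and 44, 3 and 4, 12 and 9, 6 and 10, 14 and 8, 7 and 3, 7 and 3, 11 and 3, 3 and 1, 1 and 1, and 10 and 4, in the order given. In none of the 60 called list tests did the median, the mean and the test differ in sign; they did in 30 of the 125 tests without a call, over 18 lists.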

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

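The tests of RNA integrity and of between-array scaling for the ATF4 list were chosen after its result was seen, as were the 3′ to 5′ covariate and the choice to give only list differences that hold with an estimated correlation.

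The effect of AZA differed between the 4 lines in 8010 genes by the moderated F-test. By pairwise tests of the difference it differed in 4421 genes between AML-193 and HNT-34, 3423 between AML-193 and KG1a, 6639 between AML-193 and HL60, 2130 between HNT-34 and KG1a, 5025 between HNT-34 and HL60, and 3787 between KG1a and HL60. With the 3′ to 5′ covariate these were 4401 by the F-test and 1321, 349, 192, 2333, 2276 and 1524 for the pairs in the order given, and RNA integrity is confounded with treatment in AML-193 and HL60. Among single genes the range of the log2 fold change over the lines was 6.47 for CLC, 6.27 for COL14A1, 6.27 for ZNF595, 6.02 for PRG2, 5.98 for GJA1, 5.96 for TKTL1, 5.93 for EPX, 5.37 for FABP4, 5.24 for F2RL2 and 5.06 for MAGEA4. Of the list differences between pairs of lines camera called 37. With an estimated correlation 8 held: interferon-stimulated genes (median -0.22), AML surface targets (0.46) and cholesterol synthesis genes (-1.03) for AML-193 minus HNT-34; AML surface targets (-0.26), cholesterol synthesis genes (0.64) and ATF4 and amino acid genes (-0.99) for HNT-34 minus KG1a; and ATF4 and amino acid genes for AML-193 minus KG1a (-0.87) and KG1a minus HL60 (0.66). With the covariate the median for interferon-stimulated genes was -0.33. The control probe sets, which were left out of the tested genes and served only as the covariate, had a mean 3′ minus 5′ signal of 0.722 on the HL60 AZA arrays, above that of the HL60 vehicle arrays (0.0443).

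The fold changes of AML-193 and HL60 opposed each other: of 2936 genes called in both, 2025 (69.0%) went in opposite directions. RNA integrity is a candidate explanation, since its difference between the arms ran in opposite directions in these lines. The difference between the AML-193 vehicle replicates, which received the same treatment, correlated across genes with the HL60 fold changes at r = 0.18, and that between the HL60 AZA replicates with the AML-193 fold changes at -0.17, the signs that this explanation needs. With the covariate 25 of the 2025 genes were still called in opposite directions; in AML-193 the median size of the called changes went from 0.44 to 0.27 while the standard error went from 0.096 to 0.194, and in HL60 from 0.45 to 0.36 and from 0.0945 to 0.140, so calls ended through both. Whether responses of the 2 lines also oppose each other cannot be told apart from this, because the correlation was -0.0289 after both replicate differences were regressed out, and integrity is confounded with treatment within each line.

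The ATF4 and amino acid list was lower in all 4 lines. Poorer RNA in 1 arm would move it in opposite directions in AML-193 and HL60, and the higher of its medians in these lines was -0.871. A shift from the scaling would move genes of equal signal alike, but relative to tested genes of matched mean signal the list median nearest 0 in any line was -0.20, in KG1a, where the lowest of 10000 matched resamples was -0.13 (permutation p = 0.0001). Of 100 splits that kept 2 arrays of each line in each arm, 1 gave a list median as far from 0, the real one with -0.79, and the next was -0.74. That next split kept the arms of 3 lines together, so it holds part of the treatment difference. Splits that mix the arms of a line cancel its difference between arms, which by itself moves their medians towards 0. With the list low in every line the real split was thus likely to rank first, and its rank adds little support. Nor do the splits argue against a difference between single cultures, since the 2 arrays of a group need not be separate cultures. No biological explanation was tested, and the density of the cultures and the state of the medium at harvest were not analysed here and stay open.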

How the results depend on the processing

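The 3′ to 5′ covariate, and HNT-34 against KG1a alone, were chosen after the data were seen. No paired analysis was possible because the replicate numbers pair no arrays. The genes called depend on the choice of probe set. With the probe sets of a gene averaged, 69.8% of the AML-193 calls were called again in the same direction. The share was 79.9% in HNT-34, 75.8% in KG1a and 70.4% in HL60. Among calls tested again, 5019 of 5473 in AML-193 and 5077 of 5534 in HL60 kept their sign. In HNT-34 4048 of 4091 did, and in KG1a 1327 of 1330. At an adjusted p under 0.01, as that limit implies, counts were 3726 in AML-193, 737 in KG1a, 74 shared by all 4 lines (145 at 0.05), and 2664, 1690, 1186, 3224 and 1991 for the differences AML-193 minus HNT-34, AML-193 minus KG1a, HNT-34 minus KG1a, HNT-34 minus HL60 and KG1a minus HL60. With a 2-fold minimum they were 426, 484, 142 and 490 in AML-193, HNT-34, KG1a and HL60, 104 in the mean and 7 shared. Of 185 list tests 60 were called, 31 with an estimated correlation and 129 with fry. KG1a had 844 genes on its own 4 arrays, with fewer arrays to estimate the spread. With each line as 1 replicate limma called 0 genes in the mean, and 1235 had an unadjusted p under 0.05. With the covariate, which takes up part of the difference between arms, counts were 373 in AML-193, 2149 in HL60, 4401 for the difference between lines, 39 shared, and 1321, 349, 192, 2276 and 1524 for AML-193 minus HNT-34, KG1a and HL60, HNT-34 minus HL60 and KG1a minus HL60; of the genes called without it 4146 of 4245 in HNT-34 and 1381 of 1393 in KG1a were still called. COL14A1 in AML-193 reversed with it, from 0.50 to -0.084 (adjusted p 0.926), and ITGAM in HL60 was -0.37 without probe sets of shared suffixes, where a dimmer probe set stands for it; the cause was not tested. HNT-34 against KG1a alone differed in 2130 genes, as 1 of 6 pairs. Leaving out 1 array, the lone array left being assumed to vary like the other groups, gave 688 to 1608 in KG1a (877 without vehicle array 1, 698 and 688 without AZA arrays 1 and 2), 91 to 161 shared (91 and 93 without KG1a AZA arrays 1 and 2), 2144 to 3849 for AML-193 minus KG1a (2144 without KG1a AZA array 2) and 2504 to 4141 for KG1a minus HL60 (2504 without KG1a AZA array 1). Over the same omissions the counts were 4030 to 6099 in AML-193, 2892 to 4562 in HNT-34, 4298 to 6042 in HL60 and 4883 to 5842 in the mean. Array signal has no count of molecules, and dim genes limit what can be seen: 19775 genes had a probe set and 14049 passed the filter.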

Other observations

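The comparisons of switched-on genes with dim genes were set in their present form after the result was seen, as were the genes given as examples. The splits of the arrays were planned.

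After AZA many more genes counted as switched on than off, though whether this was a response to AZA is not settled. A gene counts here as switched on if it was called and went from below the 25th percentile of the array signal (log2 5.36) with vehicle to at least the array median with AZA, and as switched off in the reverse case. In AML-193 13 genes were switched on and 0 off (exact binomial p = 0.000244), among them the scavenger receptor gene CD36, the co-receptor gene LY96, the cholesterol hydroxylase gene CH25H, the collagenase gene MMP1 and the germline gene MAGEB2. In HNT-34 19 were switched on and 0 off (exact p = 3.81e-06), including PPBP, GJA1, F2RL2, MAGEA4, MAGEA6, MAGEB2, the matrix Gla protein gene MGP and the protein S gene PROS1. In KG1a 7 were switched on and 0 off (exact p = 0.0156), namely COL14A1, CTHRC1, LPAR6, NFE4, NR5A2, TRPM4 and ZNF595. In HL60 16 were switched on, such as the stem cell factor gene KITLG, the transcription factor gene ETS1, the germline genes HORMAD1 and MAEL and the blood group gene XK, and 2 off, FCF1 and INHBE (exact p = 0.00131). Each of these binomial tests rests on limma calls from 2 arrays per arm, and genes are not independent of each other.

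An effect of the floor of the array signal cannot be told apart from a response to AZA. The planned test, the larger exact p of HNT-34 and KG1a (0.0156), only restates the excess of genes switched on. The signal distribution shared by all arrays fixes how many probe sets are dim, but not how many genes. Genes below the 25th percentile numbered 3153 with vehicle and 3026 with AZA in AML-193, and 3057 and 2959 in HNT-34. In KG1a they numbered 3018 and 2944, and in HL60 3032 and 3000. In HL60 the AZA arm had the larger 3′ minus 5′ signal. If that signal reflects poorer RNA, and poorer RNA dims genes, the ratio would turn there, and it was 16 to 2 (exact binomial p = 0.00131). These premises were assumed and not tested, and no count with the covariate is given. In AML-193, where the vehicle arm had the larger signal, the ratio was 13 to 0, the direction that these premises would give. Whether switched-on genes tend to be genes already expressed in other leukaemia lines cannot be told apart from an effect of the genes they are compared with. The share at or above the median in at least 1 of the other vehicle-treated lines was 46.2% in AML-193, 42.1% in HNT-34, 42.9% in KG1a and 37.5% in HL60. Dim genes that were not called, matched for vehicle signal, would give 8.05%, 8.28%, 4.11% and 7.64%, but most of them are low on all arrays. Those that passed the filter would give 89.7%, 94.5%, 81.9% and 85.8% (largest permutation p for a higher share of switched-on genes 1), and they passed it mostly through the other lines. DNA methylation was not analysed here, so whether these genes lost it is open.

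In 100 splits of the arrays that kept 2 arrays of each line in each arm, 1 split, the real one, gave as many genes for the mean effect (5598), and the highest of the others gave 3252. This does not argue against a difference between single cultures. With each line as 1 replicate limma called 0 genes (1235 at an unadjusted p under 0.05). That other split kept the arms of every line together, with some lines exchanged as a whole, so a high count there reflects the treatment in part. Splits that mix the arms of a line move its treatment difference into the spread, which by itself lowers their counts. For that reason the rank of the real split adds little support.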
